A study of Arabidopsis thaliana with 4 samples.

How the data were processed

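Leaf RNA of Arabidopsis thaliana was measured by RNA sequencing in 4 libraries, 1 per group: wild type (WT) air, WT R3, myc2 air and myc2 R3. Groups were taken from the sample titles. No group had a second library, so no test was run, no p-value or standard error is given, and no difference below has a replicate check. An additive model of condition and genotype would leave 1 residual degree of freedom, but only by taking the difference of responses, which is of interest here, as error, and it was left out.

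The authors deposited 1 table per library, with 1 value per AGI locus for 31319 loci. The deposited values of WT air, myc2 air and myc2 R3 are RPKM (reads per kilobase of gene and 1000000 mapped reads), per the names the submitters gave the tables. The value column of WT R3 is headed FPKM, the fragment-based form of the same unit, per the file headers, although its table is also named as RPKM. All 4 were treated as the same unit and are called RPKM below. TopHat (an aligner) and Cufflinks (a transcript quantifier) and the genome build TAIR10 are named in the submitters' processing notes, without versions. Their settings, the use of strand and the treatment of reads that match several places are not given in the sources used here, so genes that overlap on opposite strands could not be told apart.

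RPKM values are not counts, and no count test was run. Depth was estimated from the most frequent small product of RPKM and exon length, taken as 1 fragment, which in units of 1000000 fragments gives 29.2 in WT air, 27.7 in WT R3, 30.5 in myc2 air and 22.3 in myc2 R3. These estimates are approximate, because with the exon lengths of the reference used here between 16.7% and 19.2% of low genes came out within 0.02 of a whole fragment. Only products within a set window were searched, which also bounds the estimates and the counting errors that rest on them. For a gene of the median exon length, 1602 bases, a value of 1 RPKM corresponds to 46.8, 44.4, 48.8 and 35.7 fragments in these libraries, in the same order. Counting error alone is then 14.6%, 15.0%, 14.3% and 16.7% of that value. It does not cover differences between plants or between library preparations. The number of loci listed at 0 was between 8418 and 9209 per library. No locus at 0 in 1 library had 10 RPKM or more in each of the others, and no ratio of a single gene is given against a value of 0, while list medians include genes at 0 through the pseudocount.

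For each comparison of 2 libraries, the log2 ratio of each gene was computed as log2((RPKM + 1)/(RPKM + 1)), among genes with a mean of at least 1 RPKM in the libraries compared. Genes at least 2-fold apart on that scale were counted. The pseudocount understates the ratios of low genes. The difference of responses is the log2 ratio of R3 to air in myc2 less that in WT, among genes with a mean of at least 1 RPKM over the 4 libraries.

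Before the data were examined, 24 gene lists with 326 genes, the comparisons, 7 alternative settings and the rule for naming genes were fixed. Each list with at least 4 members past the filter was described by its median log2 ratio, and that median was set among those of 10000 random lists of the same size matched on mean expression in 20 bins. A list is called high or low below where its median lay outside the range from the 2.5th to the 97.5th percentile of those random lists. This placement describes these libraries only. Of 118 placements, 56 lay outside that range. Because the scaling moves the median of all genes, list medians are printed as the list median less the median of all genes in the same comparison.

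The rule for naming genes took MYC2 in every library, then the 6 highest and 6 lowest log2 ratios of each comparison among genes with a mean of at least 5 RPKM (4 and 4 for the difference of responses). It also took up to 4 members of each list, those with the largest ratios and 1 in the other direction where there was one. VTC1, VTC2, GSH1, GSH2, VSP2 and ADH1 were always taken where their lists were described. Genes outside that rule are said to be so where they appear. After the data had been seen, 4 marker lists (floral organs, cell division, secondary wall and surface wax) and 5 gene families were added for the closing part.

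The alternatives were a pseudocount of 0.1 or 5, no filter, a filter at 5 RPKM, and rescaling of each library to the median of its ratios to the geometric mean of the libraries, over genes at 1 RPKM or more in all 4, to a sum of 1000000, or to the sum without the 50 highest genes of each library. The scaling factors came from the deposited values. On simulated values for the comparison of WT R3 with WT air, with 200 genes altered, 100% of the altered genes were counted at 4-fold (16069 genes run) and 97.5% at 3-fold (16050 genes run). The simulated libraries were drawn from WT air with counting noise only, and all altered genes were raised. High recovery at a 2-fold cut was therefore to be expected. It checks the computation, not variation between plants or a shift in composition.

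Gene names came from a table for the assembly TAIR10.1, which held 30622 of the 31319 loci and not the other 697. No coordinates are printed, since the deposited tables give none and the builds differ in name. The exon sequences of the named genes were compared with those of all other genes by 50-base words. Among the genes taken by the naming rule, PRR9 shared 31.2% of its words with AT2G46670 and AT5G37940 shared 24.4% with AT5G38000, and the others shared less than 20%. HSP22 and the genes named only in the closing part were not checked for shared words or overlapping genes. Computations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with Matplotlib 3.10.9.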

Results

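The study set the transcriptome of submerged and reoxygenated Arabidopsis leaves against that of leaves kept in air, in the wild type and in myc2-2, a mutant of the jasmonate-responsive transcription factor MYC2. Its title names the question, which is whether jasmonate acts in the response to reoxygenation through antioxidant synthesis. Each of the 4 groups is 1 library, made from leaves of 6 plants of 4 weeks of age. The R3 samples are labelled as taken 3 h after submergence and the air samples as taken before it. The treatment protocol instead names 24 h of submergence in the dark and harvests at 0 and 24 h of reoxygenation, so the time behind R3 rests on the sample labels. By these labels, R3 and air also differ in a preceding 24 h of darkness and in the time of harvest. None of the 4 libraries is labelled as kept dark in air. The response named below is therefore the whole difference of R3 from air, and cannot be assigned to submergence or reoxygenation alone. Values are RPKM, in the order WT air, WT R3, myc2 air and myc2 R3 where 4 are given. No difference has a replicate check.

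In units of 1000000 fragments, the libraries held an estimated 29.2, 27.7, 30.5 and 22.3, and 16078, 17388, 16930 and 17482 genes reached 1 RPKM. Transcripts for photosynthesis took a large part of the air libraries. The 37 genes of the photosynthesis list made up 28.5% of all RPKM in WT air and 23.9% in myc2 air, against 4.55% in WT R3 and 4.15% in myc2 R3. The 50 highest genes took 39.1%, 13.3%, 33.0% and 17.3%. Across genes, the log2 values of the libraries from the same condition correlated at r = 0.98 in air and 0.97 at R3, and those of air and R3 at 0.71 in both WT and myc2. Genes are not independent replicates.

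MYC2 (AT1G32640) itself was at 45.9, 91.7, 14.2 and 34.9 RPKM. It was thus lower in both libraries labelled myc2 than in the WT library of the same condition, with log2 ratios of −1.63 in air and −1.37 at R3, and transcript was still counted in the mutant. Genes on the opposite strand overlap MYC2, COI1, ADH1, JAZ10, PYK10, CSD1, HSP17.4, DREB2A, CHS, VTE3, GALDH, EDS5, PMI1, MES18, AT4G32340 and AT2G20870 in the reference annotation, so their values are uncertain. The related factors MYC3 (30.2, 38.8, 30.6 and 38.8) and MYC4 (8.25, 12.3, 10.2 and 11.4) and the jasmonate receptor COI1 (9.06, 14.5, 8.84 and 15.4) differed less than 2-fold in every comparison, and each turned direction in at least 1 comparison under a rescaling. MYC2 and these genes as a list were inside the random range in each comparison, at 0.01 (WT response, where the direction turned under 2 rescalings), 0.23 (myc2 response), −0.22 (genotypes in air) and −0.09 (genotypes at R3) relative to all genes.

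**Figure D1:**
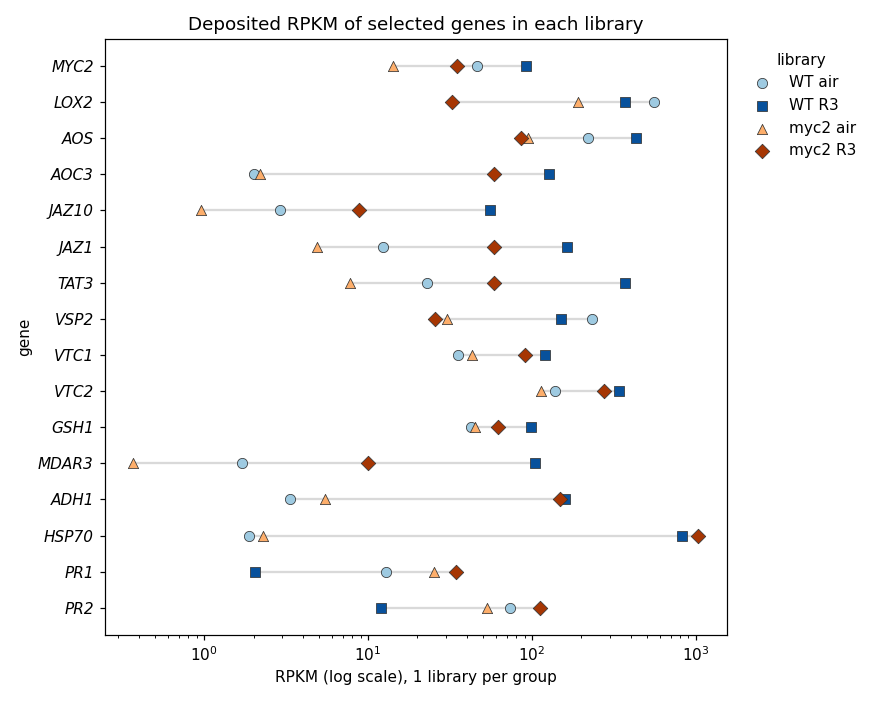
RPKM of 16 genes in each of the 4 libraries on a logarithmic axis, with 1 symbol per library and a grey line joining the lowest and highest value of each gene. MYC2 ran from 14.2 in myc2 air to 91.7 in WT R3, and the jasmonate genes LOX2 and JAZ10 were lower in myc2 R3 (32.5 and 8.83) than in WT R3 (367 and 55.5).

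In the wild type, leaves sampled at R3 carried far more transcript for heat shock proteins, oxidative stress signalling, dehydration, leaf senescence and low oxygen than leaves in air, and far less for photosynthesis and aliphatic glucosinolates. The small heat shock protein gene HSP17.6A (AT5G12030) was at 413 RPKM at R3 and 0.217 in air, and the chaperone gene HSP70 (AT3G12580) at 819 and 1.88. The chlorophyll-binding protein gene LHB1B1 (AT2G34430) was at 281 and 6354, and the carbonic anhydrase gene CA1 (AT3G01500) at 57.6 and 1811. Genes of jasmonate synthesis and its JAZ repressors were also higher at R3.

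The 6 highest ratios belonged to HSP17.6A, HSP70, HSP17.4 (AT3G46230, 0.378 in air and 383 at R3), HSP17.8 (AT1G07400, 0.462 and 387), HSP17.6II (AT5G12020, 0.195 and 267) and the protease inhibitor gene UPI (AT5G43580, 0.218 and 394). Besides LHB1B1 and CA1, the 6 lowest were FBA5 (AT4G26530, an aldolase gene, 919 and 17.3), MES18 (AT5G58310, 76.0 and 1.02), AT4G32340 (151 and 6.06) and IPMI2 (AT2G43100, 103 and 4.17). All 15 heat shock genes were higher, 14 of them at least 2-fold, and the list median was 5.75 log2 units above that of all genes. That size is set by the pseudocount, because 3 of the 15 were listed at 0 in WT air, among them HSP22 (AT4G10250), at the median, and it was 4.77 with a pseudocount of 5 and 7.57 with 0.1. The oxidative stress list was placed at 2.72, with 11 of 12 members at least 2-fold higher, among them the zinc finger gene ZAT12 (AT5G59820, 3.27 and 176) and the glutathione transferase gene GSTU24 (AT1G17170, 2.41 and 134). The abscisic acid and dehydration list stood at 2.35, with 19 of 21 members higher, such as DREB2A (AT5G05410, 1.63 and 57.6) and RD29A (AT5G52310, 14.4 and 274).

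Of the senescence and chlorophyll breakdown genes 7 of 9 were at least 2-fold higher, with a list median of 1.96. SAG21 (AT4G02380) was at 7.63 in air and 374 at R3 and the senescence regulator ORE1 (AT5G39610) at 0.912 and 24.4, while NYC1 (AT4G13250, chlorophyll b reductase) was at 112 and 81.5. Core hypoxia genes were placed high at 0.90, with 17 of 26 higher and 1 lower. The fermentation enzyme gene ADH1 (AT1G77120) was at 3.32 and 160, the haemoglobin gene HB1 (AT2G16060) at 0.840 and 79.5, and HRA1 (AT3G10040), a repressor of the low oxygen response, at 3.66 and 1.24. The salicylic acid defence list was placed high at 1.41 with 7 of 10 members higher, among them CBP60G (AT5G26920, 1.51 and 36.4), whereas the glucanase gene PR2 (AT3G57260) was at 73.4 and 12.0.

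All 37 photosynthesis genes were at least 2-fold lower at R3, with a list median of −3.32. LHCB1.2 (AT1G29910) was at 9200.2 in air and 497 at R3 and RBCS3B (AT5G38410), a Rubisco small subunit gene, at 8905 and 561. The aliphatic glucosinolate list was low at −2.40, with 11 of 14 members lower, such as CYP79F1 (AT1G16410, 84.7 and 3.69) and MAM1 (AT5G23010, 88.4 and 7.07). Superoxide dismutase and catalase genes were low at −1.44, with 5 of 10 lower, or 8 after rescaling to the median of ratios. CSD2 (AT2G28190, a plastid enzyme) was at 443 and 86.3, and the cytosolic CSD1 (AT1G08830) at 87.8 and 181.

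Among jasmonate genes, 9 of 14 biosynthesis genes and 10 of 11 JAZ repressor genes were at least 2-fold higher at R3 and none lower. After rescaling to the median of ratios these were 6 of 14 with 1 lower and 6 of 11. The list medians were 0.88 and 1.05. The allene oxide cyclase gene AOC3 (AT3G25780) was at 2.01 and 128, the peroxisomal oxidase gene ACX1 (AT4G16760) at 17.1 and 167, and the lipoxygenase gene LOX2 (AT3G45140) at 553 and 367. JAZ10 (AT5G13220) was at 2.92 and 55.5 and JAZ1 (AT1G19180) at 12.3 and 164. The biosynthesis list fell inside the random range with a pseudocount of 5 or when libraries were rescaled to an equal sum. The jasmonate response list (10 of 15 higher, 1 lower, 0.63) and the jasmonate-ethylene defence list (4 of 6 higher, 2 of 5 with the median of ratios, 0.65) were inside it, the former high with a pseudocount of 0.1, the filter at 5 RPKM or the median of ratios, with 6 of 15 then higher and 3 lower under the last. TAT3 (AT2G24850), a tyrosine aminotransferase gene, was at 22.8 and 370, and the vegetative storage protein genes VSP1 (AT5G24780) at 341 and 40.6 and VSP2 (AT5G24770) at 234 and 150.

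Genes of antioxidant synthesis went both ways, and their lists lay inside the random range. With the median of ratios, 2 of 10 ascorbate genes were higher and 2 lower, and 1 of 7 tocopherol genes higher and 2 lower. In ascorbate biosynthesis (4 of 10 higher, 1 lower, −0.37), VTC1 (AT2G39770, GDP-mannose pyrophosphorylase) was at 35.3 in air and 121 at R3 and VTC2 (AT4G26850, GDP-galactose phosphorylase) at 138 and 341, while GALDH (AT4G33670) was at 31.6 and 10.9. In glutathione synthesis and recycling (6 of 16 higher, 2 lower, −0.13), GSH1 (AT4G23100, glutamate-cysteine ligase) was at 42.3 and 98.3 and GSH2 (AT5G27380, glutathione synthetase) at 35.7 and 38.8, a direction that turned under a rescaling. The monodehydroascorbate reductase genes MDAR3 (AT3G09940, 1.69 and 104) and MDAR2 (AT5G03630, 18.5 and 316) were higher at R3, and the plastid enzyme genes DHAR3 (AT5G16710, 112 and 12.2) and TAPX (AT1G77490, 69.9 and 9.61) were lower. In tocopherol biosynthesis (3 of 7 higher, 1 lower, −0.54), TAT7 (AT5G53970) was at 7.46 and 59.5 and VTE3 (AT3G63410) at 450 and 85.7.

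The other lists were inside the random range in the wild type. These were ethylene (6 of 11 higher, 0.51), dark and sugar starvation (3 of 11 higher and 1 lower, −0.01, a direction that turned under a rescaling), circadian clock (2 of 16 higher and 2 lower, 1 and 5 with the median of ratios, −0.35, but low with the filter at 5 RPKM), indole glucosinolate (5 of 8 higher, 0.99, but high with no filter), flavonoid and anthocyanin (2 of 11 higher and 1 lower, −0.22) and reference genes (4 of 12 higher, −0.06). Among reference genes, GAPC1 (AT3G04120) was at 116 and 643 and ACT8 (AT1G49240) at 62.2 and 127, and after rescaling to the median of ratios 1 of 12 was at least 2-fold higher, with log2 ratios of 1.86 for GAPC1 and 0.41 for ACT8. Markers of root, flower and seed had fewer than 4 members past the filter, but the root beta-glucosidase gene PYK10 (AT3G09260) was at 2.91 and 62.8 and the floral gene PI (AT5G20240) at 0.609 and 11.3.

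In all, 5398 of 17271 genes were at least 2-fold higher at R3 and 1751 lower. As deposited, the median log2 ratio of all genes was 0.57. After rescaling to the median of ratios it was 0.04 and the counts were 2995 and 2959, which moved the share of higher genes from 75.5% to 50.3%, and with the 50 highest genes left out of the sum it was 65.3%.

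Compared with their own air sample, myc2 leaves at R3 had much of the WT pattern, with heat shock, oxidative stress, senescence and dehydration genes high and photosynthesis genes low. Unlike in WT, jasmonate synthesis genes lay inside the random range and flavonoid genes were low. The 6 highest ratios were all heat shock genes, with HSP17.6A at 0.0520 RPKM in air and 977 at R3 and HSP70 at 2.27 and 1034. Across 17540 genes the log2 responses of the genotypes, which share no library, correlated at r = 0.92 (Spearman 0.90), and 3722 genes were at least 2-fold higher in both, against 1271 if the lists of each were independent, and 1433 lower in both, against 199. With the median of ratios these were 2385 against 517 and 2207 against 459.

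The heat shock list was placed at 7.15 in myc2 (5.37 with a pseudocount of 5 and 8.42 with 0.1), oxidative stress signalling at 3.38, senescence at 3.12, abscisic acid at 2.05, salicylic acid defence at 2.03, hypoxia at 0.92 and the JAZ repressors at 0.74, all high. With the filter at 5 RPKM the JAZ list was inside the random range. Photosynthesis (−2.70), aliphatic glucosinolates (−2.54), flavonoids and anthocyanins (−1.39) and superoxide dismutases and catalases (−0.99) were low, the last not under 2 of the 3 rescalings or the filter at 5 RPKM. Of flavonoid genes, 6 of 11 were at least 2-fold lower, such as chalcone synthase CHS (AT5G13930, 222 in air and 35.0 at R3) and LDOX (AT4G22880, 9.97 and 1.87), and PAP2 (AT1G66390) was at 0.497 and 3.34. The 6 lowest ratios were FBA5 (642 and 16.2), AT1G66100 (658 and 17.0), ENODL14 (AT2G25060, 39.6 and 0.312), AT5G16250 (43.2 and 0.628), AT3G02640 (25.9 and 0.163) and CA1 (1114 and 48.1).

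Jasmonate biosynthesis lay at 0.09 in myc2, with 5 of 14 members higher and 2 lower (3 and 2 with the median of ratios), and turned to −0.02 with the filter at 5 RPKM. AOC3 was at 2.18 and 58.9 and LOX2 at 190 and 32.5. The jasmonate response list (6 of 13 higher and 2 lower, 0.68) held ST2A (AT5G07010, 0.988 and 29.8) and VSP1 (153 and 13.2), with VSP2 at 30.1 and 25.4, and its median turned to −0.08 with that filter. VTC1 was at 43.2 and 90.9, VTC2 at 114 and 273, GSH1 at 44.8 and 61.7, GSH2 at 38.7 and 26.3 and ADH1 at 5.47 and 147. The lists of ascorbate (−0.36), glutathione (−0.04, turning under a rescaling), tocopherol (−0.23), jasmonate-ethylene defence (−0.66), ethylene (0.22), dark and sugar starvation (0.41), circadian clock (−0.11), indole glucosinolate (0.55, but high with an equal sum), root, flower and seed markers (−0.10, but low with no filter) and reference genes (0.01, also turning) were inside the random range. In all, 4175 of 17737 genes were higher and 2031 lower. The median log2 ratio of all genes was 0.30, and 0.03 after rescaling to the median of ratios, when the share of higher genes moved from 67.3% to 51.9%. Without the 50 highest genes in the sum it was 56.0%.

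**Figure D2:**
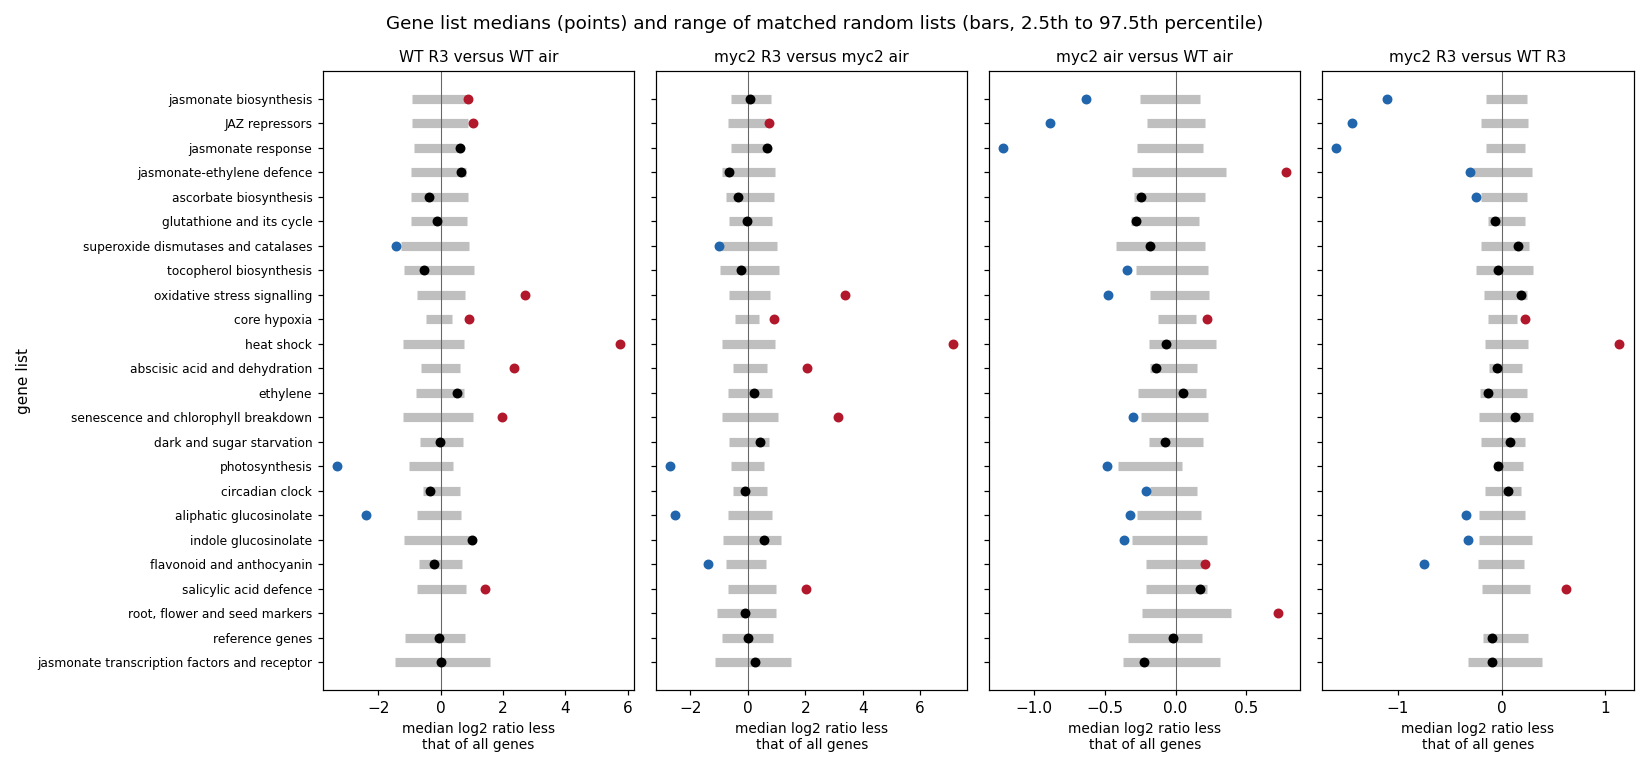
Median log2 ratio of each gene list less that of all genes (x axis, points) in the 4 comparisons of 2 libraries, 1 panel each, with grey bars for the range that held 95% of 10000 matched random lists. Red points lie above the bar, blue points below it and black points inside, and a list with fewer than 4 genes past the filter has none. The heat shock list lies at 5.75 and 7.15 in the responses, and the jasmonate response list at −1.59 between the genotypes at R3.

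Before submergence, myc2 leaves had less transcript of jasmonate genes than WT leaves, and more of some single genes of lipid transfer, wax and defence. Jasmonate response genes were low as a list at −1.22, JAZ repressors at −0.88 and jasmonate biosynthesis at −0.63. VSP2 was at 234 RPKM in WT and 30.1 in myc2, CORI3 (AT4G23600, cystine lyase) at 196 and 46.3, LOX2 at 553 and 190 and AOC2 (AT3G25770) at 373 and 154. The jasmonate-ethylene defence list was instead high at 0.78, with the defensin gene PDF1.2b (AT2G26020) at 1.97 and 9.34 and the factor ORA59 (AT1G06160) at a log2 ratio of 1.25.

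Of 12 jasmonate response genes 6 were at least 2-fold lower, of 10 JAZ genes 3 (5 with the median of ratios) and of 14 biosynthesis genes 4, and none of these lists had a member 2-fold higher. JAZ1 was at 12.3 and 4.86, JAZ5 (AT1G17380) at 5.84 and 2.04, and LOX6 (AT1G67560) at 4.67 and 8.47. The 6 lowest ratios were VSP2, CORI3, AT1G14250 (17.3 and 1.59), the beta-amylase gene BAM5 (AT4G15210, 95.4 and 12.7), AT4G17470 (11.9 and 1.91) and AT1G73325 (39.4 and 8.24). The 6 highest were AT5G37940 (0.307 and 48.9), the lipid transfer protein genes LTP4 (AT5G59310, 5.48 and 102) and LTP3 (AT5G59320, 8.61 and 84.7), the wax alkane hydroxylase gene CYP96A15 (AT1G57750, 2.59 and 48.2), AT2G20870 (10.1 and 75.9) and AT2G33850 (5.99 and 47.0). AT5G37940 shares 24.4% of its 50-base words with AT5G38000.

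Beside these, the 4 root, flower and seed markers past the filter were all higher in myc2 air, at 0.72 as a list, none of them 2-fold. The floral genes AP3 (AT3G54340), SEP3 (AT1G24260) and PI were at 0.651, 1.36 and 0.609 in WT and 2.27, 3.27 and 2.08 in myc2, and PYK10 was at 2.91 and 6.54. Hypoxia genes (4 of 20 higher, 1 of 20 with the median of ratios, 0.22) were also placed high, with HB1 at 0.840 and 3.76 and ADH1 at 3.32 and 5.47, though not with the filter at 5 RPKM. Flavonoid genes (0.21) were high as deposited but not under 5 of the 7 alternatives, with FLS1 (AT5G08640) at 14.9 and 33.8.

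Low lists with no member 2-fold apart were oxidative stress signalling (−0.47), photosynthesis (−0.48), indole (−0.37) and aliphatic glucosinolates (−0.32), tocopherol (−0.35), senescence (−0.30) and circadian clock (−0.21), with aliphatic glucosinolates and the clock inside the range with the filter at 5 RPKM. RBCS2B (AT5G38420) was at 4102 and 2719.7 and ELF4 (AT2G40080) at 85.7 and 52.7. Ascorbate (−0.24) and glutathione (−0.28) genes were inside the random range, with VTC1 at 35.3 and 43.2, VTC2 at 138 and 114, GSH1 at 42.3 and 44.8 and GSH2 at 35.7 and 38.7. The directions of VTC1, GSH1 and GSH2 turned under at least 1 rescaling. Superoxide dismutases and catalases (−0.18), heat shock (−0.07), abscisic acid (−0.14), ethylene (0.06), dark and sugar starvation (−0.07), salicylic acid defence (0.17, high with a pseudocount of 0.1 or the median of ratios) and reference genes (−0.02) were inside the range.

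In all, 410 of 16616 genes were higher in myc2 air and 57 lower, a share of 87.8% higher. The median log2 ratio of all genes was 0.22, and −0.03 after rescaling to the median of ratios, when the counts were 215 and 127 and the share 62.9%. Without the 50 highest genes in the sum the counts were 339 and 81, and with an equal sum 668 and 73.

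At R3, the jasmonate pathway was much lower in myc2 than in WT from the first enzymes to the response genes, and heat shock and salicylic acid defence genes were higher. LOX2 was at 367 RPKM in WT and 32.5 in myc2, the allene oxide synthase gene AOS (AT5G42650) at 432 and 85.3, AOC2 at 399 and 68.0 and AOC1 (AT3G25760) at 131 and 28.7. MDAR3 of the ascorbate-glutathione cycle, at 104 in WT, had a log2 ratio of −3.25. The pathogenesis-related genes PR1 (AT2G14610) and PR2 were at 2.04 and 12.0 in WT and 34.2 and 111 in myc2.

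Every jasmonate biosynthesis, JAZ and jasmonate response gene that passed the filter was lower in myc2 R3, and 8 of 14, 9 of 11 and 12 of 15 of them at least 2-fold. The log2 ratio nearest to no change among them was −0.01, in a biosynthesis gene. The lists were low at −1.11, −1.44 and −1.59. JAZ10 was at 55.5 and 8.83, JAZ5 at 52.0 and 12.3, TAT3 at 370 and 58.3, the jasmonate hydroxylase gene CYP94B3 (AT3G48520) at 25.6 and 2.65, the chlorophyllase gene CLH1 (AT1G19670) at 243 and 37.7 and VSP2 at 150 and 25.4. The jasmonate-ethylene list was low at −0.31, with PDF1.2a (AT5G44420) at 11.8 and 0.930. The 6 lowest ratios were LOX2, MDAR3, AT5G19110 (44.2 and 2.42), the methyltransferase gene FAMT (AT3G44860, 377 and 35.9), AT1G66100 (177 and 17.0) and the methionine sulfoxide reductase gene MSRB7 (AT4G21830, 58.3 and 5.51).

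Ascorbate biosynthesis genes were low as a list at −0.25 with none 2-fold apart, and glutathione genes lay inside the random range at −0.06 with 2 of 17 lower. VTC1 was at 121 in WT and 90.9 in myc2, VTC2 at 341 and 273, PMI1 (AT3G02570) at 41.1 and 22.4, GSH1 at 98.3 and 61.7, GSH2 at 38.8 and 26.3 and DHAR1 (AT1G19570) at 489 and 214. Flavonoid and anthocyanin genes were low at −0.75, with 5 of 11 lower, among them LDOX (14.0 and 1.87), the reductase gene DFR (AT5G42800, 8.91 and 2.04) and UF3GT (AT5G54060, 3.48 and 0.421). Indole (−0.32) and aliphatic (−0.35) glucosinolate genes were low too, the latter not with the filter at 5 RPKM. MYB34 (AT5G60890), an indole glucosinolate regulator, was at 30.3 and 9.12.

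The heat shock list was high at 1.14 and all 15 members were higher in myc2 R3, 10 at least 2-fold. HSP21 (AT4G27670) was at 11.5 and 36.4 and HSP18.2 (AT5G59720) at 239 and 612. Salicylic acid defence was high at 0.62 with 3 of 10 higher, PR1, PR2 and ICS1 (AT1G74710, isochorismate synthase, 11.8 and 28.6), and EDS5 (AT4G39030) was at 16.4 and 12.5. The 6 highest ratios were PR1, PR2, AT4G37290 (2.01 and 30.9), PNP-A (AT2G18660, 6.10 and 56.3), AT4G10500 (0.717 and 12.6) and AT1G13609 (1.37 and 17.3). Hypoxia genes were high at 0.22 with 3 of 26 higher, such as AT3G10020 (171 and 395), with ADH1 at 160 and 147. The root marker PYK10 was at 62.8 and 11.4 and PI at 11.3 and 17.0.

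Lists inside the random range at R3 were oxidative stress signalling (0.18), superoxide dismutases and catalases (0.16), tocopherol (−0.04), abscisic acid (−0.05), ethylene (−0.13), senescence (0.13), dark and sugar starvation (0.08), photosynthesis (−0.03), circadian clock (0.06) and reference genes (−0.09). In all, 335 of 17491 genes were higher in myc2 R3 and 280 lower. Rescaled to an equal sum, the counts were 305 and 459, so that the share of higher genes moved from 54.5% to 39.9%, and the median log2 ratio of all genes from 0.04 to −0.08. The genotype ratios in air and at R3, which share no library, correlated at r = 0.09 (Spearman 0.01) across genes, but 29 genes were at least 2-fold lower in myc2 in both, against 0.82 if independent, and 28 higher in both, against 7.30. With the median of ratios these were 47 against 1.84 and 19 against 3.48.

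Among the 24 lists fixed before the data were examined, the responses of the genotypes differed most in heat shock genes, which stood higher in myc2, and in jasmonate-ethylene defence and flavonoid genes, which stood lower, followed by the jasmonate pathway. The single genes furthest apart included a lipid transfer protein gene, a wax gene and the defence gene PR2. The 4 lowest differences (myc2 less WT) were LTP4 (5.48, 216, 102 and 62.3 RPKM), AT5G37940 (0.307, 10.6, 48.9 and 10.1), CYP96A15 (2.59, 13.1, 48.2 and 5.70) and the arabinogalactan gene FLA12 (AT5G60490, 2.32, 21.5, 14.5 and 4.96), each of which was already higher in myc2 air than in WT air. The 4 highest were PR2 (73.4, 12.0, 53.5 and 111), AT4G37290 (0.0596, 2.01, 0.229 and 30.9), LSU1 (AT3G49580, 7.90, 1.75, 4.26 and 13.5) and AT3G55790 (0.110, 3.01 and 21.4 in WT air, WT R3 and myc2 R3, and listed at 0 in myc2 air).

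Jasmonate biosynthesis (−0.73), JAZ repressors (−0.66), jasmonate response (−0.51), jasmonate-ethylene defence (−1.11) and flavonoid genes (−1.05) were low in this difference. The log2 response of LOX2 was −0.59 in WT and −2.51 in myc2, that of JAZ10 3.85 and 2.33 and that of CYP94B3 4.31 and 1.78. As deposited, the responses of VTC1, GSH1 and GSH2 differed by −0.69, −0.75 and −0.65 and that of VTC2 by −0.04 (turning under a rescaling). From these 4 values the median of all genes was not taken off. It was −0.16 as deposited and 0.07 after rescaling to the median of ratios, so the size of these gaps depends on the scaling. With that median taken off, the ascorbate (0.04) and glutathione (0.08) lists were inside the random range. Heat shock (1.29), oxidative stress signalling (0.61) and photosynthesis (0.43) genes were high, the last not with the filter at 5 RPKM. Between the genotypes, oxidative stress signalling and photosynthesis lay inside the random range at R3 (0.18 and −0.03) and were low in air (−0.47 and −0.48). The jasmonate-ethylene list was at 0.78 in air and −0.31 at R3. The differences of these 3 lists thus rest more on the air samples. Salicylic acid defence was high at 0.36 as deposited and inside the range under 5 of the 7 alternatives, the 3 rescalings among them. The others lay inside it, between −0.22 (ethylene) and 0.26 (circadian clock, high with a pseudocount of 0.1 or the median of ratios), hypoxia genes (−0.06) were low with a pseudocount of 0.1, and that of aliphatic glucosinolate genes (0.01) turned under a rescaling.

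In all, 912 of 17540 genes had a response at least 2-fold smaller or more negative in myc2 and 264 at least 2-fold larger. The median difference was −0.16, and 0.07 after rescaling to the median of ratios, when the counts were 525 and 498. The share of positive differences was 22.4% as deposited, 48.7% after that rescaling and 12.1% after rescaling to an equal sum.

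**Figure D3:**
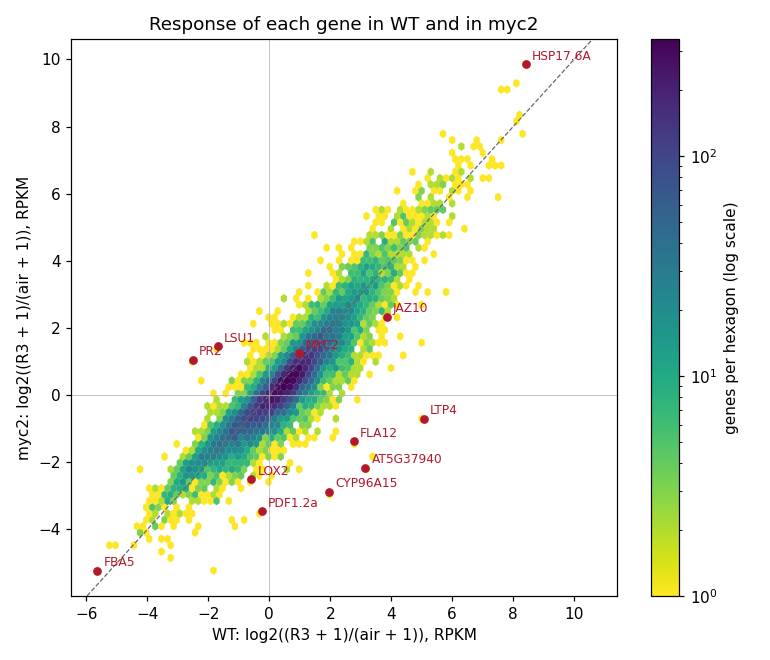
Log2 ratio of R3 to air in WT (x axis) and in myc2 (y axis) for 17540 genes with a mean of at least 1 RPKM, as hexagons coloured by the number of genes on a logarithmic scale, with 12 named genes in red. The dashed line marks equal responses, r was 0.92 across genes, and LTP4, FLA12, AT5G37940 and CYP96A15 lie below the line while PR2 and LSU1 lie above it.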

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

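Among the named genes, the following were singled out because their ratios of R3 to air were at least 2-fold and opposite in sign in the 2 genotypes. With 1 library per group the difference between the responses was not tested, and no test of an explanation was run for single genes.

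CYP96A15 (AT1G57750), which hydroxylates wax alkanes, had log2 ratios of 1.97 in WT and −2.88 in myc2, a difference of −4.85. FLA12 (AT5G60490), a fasciclin-like arabinogalactan gene, had 2.76 and −1.38, a difference of −4.14. AT5G37940 had 3.15 and −2.17, a difference of −5.33, and shares 24.4% of its 50-base words with AT5G38000. Each of these genes was higher in myc2 air than in WT air (48.2, 14.5 and 48.9 RPKM against 2.59, 2.32 and 0.307), and at R3 they were at 5.70, 4.96 and 10.1 in myc2 and 13.1, 21.5 and 10.6 in WT.

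PDF1.2b (AT2G26020), a defensin gene, had 1.11 in WT and −1.05 in myc2, a difference of −2.16, from 1.97 and 5.39 RPKM in WT air and R3 and 9.34 and 3.99 in myc2. PR2 (AT3G57260) had −2.52 and 1.05, a difference of 3.56, with 73.4 and 12.0 RPKM in WT and 53.5 and 111 in myc2. LSU1 (AT3G49580), a gene of the response to low sulfur, had −1.69 and 1.46, a difference of 3.15, with 7.90 and 1.75 RPKM in WT and 4.26 and 13.5 in myc2. Among all 17540 genes compared, 15 were at least 2-fold apart in opposite directions, 13 of them higher at R3 in WT and lower in myc2 and 2 the reverse.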

How the results depend on the processing

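The 7 alternatives were all fixed before the data were examined. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, and for the same reason no library could be left out. The recomputed counts were those of genes at least 2-fold apart and of lists outside the random range. Of these, 52 stayed within 1.5 times the count as deposited and 25 did not. Of the lists outside the random range as deposited, none turned relative to all genes under any alternative in which it could be placed, and 21 placements moved inside the range. Some of these lists had too few members past the filter at 5 RPKM to be placed there. Among lists inside it, 12 placements moved outside and 44 medians, relative to all genes, turned. No named gene at least 2-fold apart turned, 89 values fell below 2-fold and 51 that had been below it passed it. The causes were not tested except where a setting itself shrinks ratios or removes genes.

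A pseudocount of 5, which shrinks the ratios of low genes, gave 3157 higher and 1134 lower genes for the WT response, 2613 and 1125 for the myc2 response, 100 and 29 for the genotypes in air, 157 and 135 at R3, and 131 and 334 for the difference of responses. A pseudocount of 0.1 gave 923 and 97 in air, 524 higher at R3 and 1538 lower differences. The filter at 5 RPKM, which removes genes, left 233 higher in air and 589 lower differences. Rescaling to the median of ratios gave 2995 and 2959 for the WT response, 215 and 127 in air, and 498 and 525 for the difference. Rescaling to an equal sum gave 668 higher in air, 459 lower at R3 and 1784 lower differences.

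Before the median of all genes was taken off, that of circadian clock genes in air turned from 0.01 to −0.0073 with the filter at 5 RPKM, −0.25 with the median of ratios and −0.0737 without the 50 highest genes in the sum. That of aliphatic glucosinolate genes in air turned to 0.0794 with the filter at 5 RPKM, and that of salicylic acid defence in the difference of responses to −0.0097 with an equal sum. A rescaling moves all genes nearly alike, and relative to all genes these lists kept their direction: the clock list was between −0.22 and −0.21 under the rescalings and −0.21 with the filter, aliphatic glucosinolate genes were at −0.12 with the filter, and salicylic acid defence was at 0.32 with an equal sum. Depth gives a counting error of 14.3% to 16.7% at 1 RPKM for a gene of median length, and variation between plants or preparations was not measured.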

Other observations

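The gene families, marker lists and single genes named in this part, and the explanations weighed, were chosen after the data had been seen. So were the tests of floral tissue alone, of scaling and of a larger overall response for heat shock genes, and both tests on plastid-encoded genes, while the other tests were set before their results were seen.

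Growth genes and stress regulators not covered above also differed between air and R3. WRKY transcription factors stood 1.81 log2 units above all genes in WT, with 44 of 51 at least 2-fold higher and none lower, and 2.16 in myc2, with 43 of 53 higher. Tau class glutathione transferases stood at 1.80 and 2.27, with 18 of 24 at least 2-fold higher and 2 lower in WT, and 17 of 23 higher and 3 lower in myc2. Histone genes lay at −1.27 and −1.07, each with 8 of 19 lower, and SAUR genes, a family of auxin-induced growth genes, at −1.09 and −2.00. Mitotic genes lay at −2.31 in WT, where 5 of 10 passed the filter, and at −2.41 in myc2, where 9 of 10 did. The 2 values thus rest on different genes, and all that passed were at least 2-fold lower. Levels at R3 were near the floor, so passing rested on the air value. CYCB1;1 (AT4G37490) and CDKB1;1 (AT3G54180), which did not pass in WT, had log2 ratios of −0.56 and −0.64 there. In the difference of the responses 9 of 10 passed and the list was low at −0.70. In air it was higher in myc2 than in WT, at 0.74. The cytokinesis gene KNOLLE (AT1G08560) was at 9.03, 0.563, 24.1 and 1.12 RPKM in WT air, WT R3, myc2 air and myc2 R3, and CDC20.1 (AT4G33270) at 4.60, 0.236, 11.6 and 0.496. Expansins lay inside the random range in WT (−0.17) and low in myc2 (−1.23).

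Genes of the surface wax were higher at R3 in WT, 6 of 6 at least 2-fold (4 of 6 with the median of ratios) with a list median of 1.57. They were inside the random range in myc2 at 0.32. In the difference of the responses wax genes stood at −1.47 and secondary wall genes, 4 of 7 past the filter, at −1.26. Wax genes were already high in myc2 air against WT air, at 1.07 with 4 of 6 at least 2-fold higher. Between the genotypes at R3 they lay at −0.54 with none 2-fold apart, so the air samples carried more of that difference. CER3 (AT5G57800) was at 16.1, 118, 30.7 and 73.2 RPKM and CER1 (AT1G02205) at 19.8, 66.3, 52.0 and 52.2. Genes of the secondary wall were lower in myc2 R3 than in WT R3, 4 of 6 at least 2-fold at −1.06 as a list, but 2 of 5 after rescaling to the median of ratios, and most of them were near the filter at 1 RPKM, with the laccase gene LAC4 (AT2G38080) at 1.74, 8.86, 2.81 and 1.89 RPKM.

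More genes were higher than lower in myc2 air against WT air, 410 against 57. Rescaling to the median of ratios left 62.9% of the genes at least 2-fold apart on the higher side. The other rescalings kept more of the excess. With the 50 highest genes left out of the sum, 339 were higher and 81 lower, and with an equal sum 668 and 73. Scaling may thus account for some of the excess, but how much depends on the rescaling. Scaling and a true excess cannot be told apart from these values. Values after rescaling in the rest of this paragraph use the median of ratios. More dividing or stem tissue in the myc2 air sample is a candidate explanation that these values cannot decide. The added genes had a median log2 ratio of 0.67 after rescaling (that of all genes, −0.03, not taken off), with 21 of 22 higher. They mix 10 division, 6 wax, 4 wall and 2 floral genes, in lists chosen after the data had been seen. CYP96A15, a wax gene, had already been seen among the highest ratios of this comparison, so the wax genes are no separate support. The wall genes alone lay inside the random range, so the median of 0.67 does not point to stem tissue. It was not tested whether the added genes account for the excess. Floral tissue cannot be told apart. The markers AP3, SEP3 and PI, which raised the idea, were higher. Their list of root, flower and seed markers, which also holds the root gene PYK10, stayed high after rescaling at 0.81, but it is no separate support. PI and PYK10 were also higher in the R3 than in the air library of both genotypes. Whether the treatment or the tissue content of the samples lies behind that was not tested. Only SEP1 and SEP2 of 10 added floral genes passed the filter, with a median of −0.15 before that of all genes was taken off. SEP1 (AT5G15800) was at 2.60 RPKM in WT and 1.66 in myc2. WT air leaves also expressed 9 of 10 division, 6 of 6 wax and 3 of 7 wall genes at 1 RPKM or more, and an effect of the genotype on these groups remains open and was not tested.

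Heat shock genes were higher in myc2 R3 than in WT R3, all 15 of them. Scaling by 1 factor per library shifts all genes nearly alike. It is argued against, since the list median as deposited lay 1.14 above that of all genes. Over the deposited scale and the 3 rescalings the lowest such value was 1.13, above the random range each time. A rescaling hardly moves this value, so the 3 are not separate checks. A larger response of the myc2 R3 sample as a whole is argued against as the only cause, as the median of 1565 other genes at least 4-fold higher at R3 on average lay 0.20 above that of all genes. A part of the difference may still come from it, since 142 of these were 2-fold higher and 55 lower, and the median was 0.42 for the 139 with a mean log2 response from 4 to 5 and 0.35 for the 41 at 6 or more. A genotype effect on heat shock genes is a hypothesis that may hold, and a difference in handling or time between the samples remains open and was not tested.

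Plastid-encoded genes were higher in myc2 R3 than in WT R3, with ATCG00220 at 6722 RPKM in WT and 25348 in myc2 and ATCG01020 at 4392 and 9693. Plastid loci took 3.11% of all RPKM in WT R3 and 7.47% in myc2 R3, most of the difference from these 2 loci (ATCG00220 1.27% and 4.35%, ATCG01020 0.832% and 1.66%), the nuclear photosynthesis list did not stand apart (−0.03), and in air the plastid genes were instead low in myc2 (−0.45, with 20 of 75 higher, or 5 after rescaling). Scaling is argued against, since the median of the plastid genes as deposited lay 0.37 above that of all genes. On the same scales as above the lowest such value was 0.36, above the random range each time. Here too the rescalings hardly move the value and are not separate checks. A higher yield of plastid RNA as a class could be the source and cannot be told apart from changes in single genes, since 73.5% of 68 plastid genes were higher after rescaling and the others were not. How RNA was selected for the libraries is not given in the sources used here, and no biological explanation was tested.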
